A study of Mus musculus with 12 samples.

How the data were processed

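RNA was measured in 12 samples of EMRK1184luc cells, in 4 groups of 3: DMSO vehicle or 5 µM WM-1119, for 3 or 6 days. Per the labels the cells were grown in high-glucose DMEM, RNA was isolated on RNeasy columns and libraries were made with a TruSeq stranded kit for messenger RNA, which selects poly(A) RNA. The design text of the series calls the 3 samples of a group biological replicates. It gives no culture, day or batch for them, so the p-values measure the spread between these samples as they were prepared.

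The deposited table holds read counts per gene for each of the 12 libraries, which the authors made from the aligned reads; all values are whole numbers and no normalization was applied to them. The submitters' processing notes name featureCounts, with no version, and the mouse genome build mm10. The aligner, the strand setting, and how reads that map to several places or overlap several genes were treated are not given in the sources used here. These choices bear most on genes with close paralogs or processed pseudogenes. The table has 27179 entries. Of these 874 carry no gene identifier and were left out, and they held 0.305% to 0.362% of the counts of a library. Symbols and positions of 25275 of the 26305 Entrez identifiers came from the RefSeq annotation of the same build, and 1030 had no match. Every column of the table was mapped to a sample by the title of the sample.

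Counts were scaled with TMM factors, genes with low counts were removed with filterByExpr by group, and 11997 genes were tested, 205 of them without a symbol. All 12 libraries entered 1 quasi-likelihood fit with 4 group means and robust prior (edgeR 4.0.16, R 4.3.3). The contrasts were WM-1119 against DMSO at 3 days, at 6 days and averaged over both times, the difference between those effects, and DMSO at 6 days against DMSO at 3 days. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes of a contrast, with a threshold of 0.05. An exact permutation of 3 libraries against 3 cannot give a p below 0.1, so the model that shares the spread between genes was used. The common biological coefficient of variation was 5.69% and the median prior degrees of freedom 11.8. Fold changes are model estimates, and errors of log2 fold changes are standard errors. Levels are CPM, counts scaled by the library total times its TMM factor, as mean and SD of 3 libraries. A fold against a group at 0 counts was computed against a floor of 3 counts over the group, which covers counting error only.

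A set of 33 gene lists (pathways, complexes and markers of B cells and of other cell types) with 987 members was written before the data were examined, as were the comparisons, the tests and the alternatives except where stated; 985 members were matched and 788 tested. Lists with at least 5 tested genes were compared with all other genes by camera on voom values (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The named genes follow a fixed rule. For each time these are the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM whose 3 treated libraries all lie on 1 side of the 3 controls. Next come the 4 rises and 4 falls with the smallest p, up to 4 members with the smallest p of each described list, and a fixed set of genes of the KAT6 complexes, the cell cycle, MYC, p53 and sex-linked transcripts. For the difference between times and the DMSO comparison they are the 4 rises and 4 falls with the smallest p. Of the fixed set 1 gene is not reported here. Genes without an assigned name were left out, and names outside the rule are marked as chosen after their values were seen.

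The test was checked on simulated data, counts drawn from the measured means, dispersions and library sizes with known changes added at 3 days. It called 54% of 50 genes changed 1.25-fold, 86% of 50 changed 1.5-fold, 91.8% of 49 changed 2-fold and 100% of 50 changed 4-fold, and 14 of its 179 calls were genes left unchanged (7.82%). The changed genes were few among the 11890 tested there, while 24.5% and 30.7% of genes were called at 3 and 6 days in the measured data. The shares found and the share of false calls depend on that fraction. Of 20 unchanged lists of randomly chosen genes 0 were called. The simulated genes were drawn independently of each other. The result therefore does not show how the preset correlation of 0.01 performs on lists whose genes vary together. The alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. A further 3 were chosen after the data had been seen: all libraries thinned to 14691369 counts, leaving out the 5 libraries with over 1 CPM of Col1a1, and the replicate number as a block for the libraries of 6 days alone. The labels give no source for a pairing by replicate number. The correlations of the deviations from the group mean between same-numbered DMSO and WM-1119 libraries were 0.33, 0.42 and 0.23 at 6 days, where those of other numbers were below 0, so the numbers pair the samples of 6 days by this measure. At 3 days they were -0.01, 0.11 and -0.03, and the numbers do not pair those. Over both times 7 of 12 libraries were closest to a library of their own number. The main fit has no block.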

Results

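The data are messenger RNA profiles of EMRK1184luc, a luciferase-expressing B cell lymphoma line that arose in a female Eµ-Myc mouse, whose transgene drives Myc from the immunoglobulin heavy chain enhancer. Cells were grown with 5 µM WM-1119, an inhibitor of the histone acetyltransferases KAT6A and KAT6B, or with its vehicle DMSO, and collected after 3 or 6 days of treatment. The 4 groups hold 3 biological replicates each. Library totals were 17928095 to 21712496 counts with DMSO and 18327651 to 28228807 with WM-1119 at 3 days. At 6 days they were 22831687 to 41749357 with DMSO and 14736267 to 17563985 with WM-1119. Mitochondrially encoded transcripts took 2.46% to 3.47% of the counts of a library. The lowest Pearson correlation of log2 CPM (counts scaled by the library total times its TMM factor) between replicates, across genes, was 0.993. In a multidimensional scaling of the 12 libraries the first dimension, with 45.5% of the variance, put the 6 DMSO libraries between -0.71 and -0.65 and the 6 WM-1119 libraries between 0.49 and 0.85. The second dimension held 13.4%. There replicates 1, 2 and 3 of 6 days lay at 0.46, 0.74 and -0.26 with WM-1119 and 0.39, 0.26 and -0.001 with DMSO. The libraries of 3 days lay between -0.54 and -0.04, so this dimension did not follow time alone.

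Transcripts of the inhibitor's own targets did not pass the test at either time. Kat6a had 170 ± 7.27 CPM with DMSO and 170 ± 10.9 CPM with WM-1119 at 3 days (SD, n = 3 each; log2 fold change 0.01 ± 0.05, SE; adjusted p = 0.928), and its log2 fold change at 6 days was 0.10 ± 0.05 (adjusted p = 0.129). Kat6b, the less abundant of the pair with 25.8 ± 1.30 CPM in DMSO at 3 days, had log2 fold changes of 0.06 ± 0.07 and -0.04 ± 0.07 (adjusted p = 0.580 and 0.681). Among the other subunits of the KAT6 complexes, Brpf3 rose at both times, by 0.35 and 0.23 on the log2 scale. Meaf6 rose at 3 days by 0.20 (adjusted p = 0.0243), a call that was lost without DMSO replicate 1 (0.109) or 2 (0.0743) or WM-1119 replicate 1 (0.0799) or 3 (0.0694) of 3 days and with all libraries thinned to the same depth (0.0976). Of the 8 complex members tested, 2 were higher and 0 lower at 3 days, and 1 higher and 0 lower at 6 days. The list was not called by camera (adjusted p = 0.154 and 0.342), but fry, which does not compare with other genes, called it at 3 days (adjusted p = 0.00907). Xist, transcribed from the inactive X chromosome, was present in all 4 groups, with group means of 1867 and 1567 CPM with DMSO and of 2179 and 1641 CPM with WM-1119 at 3 and 6 days. It did not pass the test at either time. The Y-linked genes Ddx3y and Eif2s3y had 5 and 4 counts in total over the 12 libraries.

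The comparison at 3 days asked which transcripts differ after the shorter exposure to the inhibitor. Neurl3, which encodes a ubiquitin ligase (chromosome 1, 36264602 to 36274674, mm10), rose 5.37-fold, from 6.14 ± 0.656 to 33.0 ± 2.50 CPM (SD, n = 3 each; log2 fold change 2.43 ± 0.09, SE; adjusted p = 3.49e-13). Hoxb8, a homeobox transcription factor gene (chromosome 11, 96279401 to 96285325), fell 3.36-fold, from 173 ± 7.31 to 51.4 ± 0.438 CPM (log2 fold change -1.75 ± 0.05; adjusted p = 1.12e-15). Scd1, which encodes a stearoyl-CoA desaturase that makes monounsaturated fatty acids (chromosome 19, 44394450 to 44407709), fell 3.60-fold, from 136 ± 6.15 to 37.8 ± 2.90 CPM (adjusted p = 3.83e-14). The neighbouring desaturase gene Scd2 fell 2.07-fold, from 609 ± 44.5 CPM, and Gpam, whose product starts glycerolipid synthesis, fell 1.92-fold, from 216 ± 8.96 CPM.

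The prostacyclin receptor gene Ptgir rose 4.25-fold at 3 days, from 1.98 ± 0.234 to 8.50 ± 1.45 CPM. The early lymphoid surface marker Ly6d rose 4.13-fold and the cadherin gene Cdh17 3.31-fold. Dusp5, which encodes a phosphatase of ERK, rose 2.09-fold, from 48.8 ± 4.39 to 102 ± 6.98 CPM, and Rasgrp2, which encodes an exchange factor for Rap GTPases, rose 1.80-fold. Igip, Dstyk and Cfp rose by 1.64, 1.57 and 1.55 on the log2 scale. Large falls were those of the junctional adhesion molecule gene Jam2 (5.04-fold), the nuclear receptor gene Nr4a3 (4.29-fold), the histone deacetylase gene Hdac9 (3.98-fold) and Ndrg1 (3.68-fold). The largest falls among the named genes were those of Slc16a3, a lactate transporter gene (8.56-fold, from 23.8 ± 14.2 to 2.81 ± 0.165 CPM; adjusted p = 0.00571), and of the hypoxia-inducible gene Ankrd37 (8.28-fold, from 10.2 ± 7.26 CPM; adjusted p = 0.0228). Both varied widely between the DMSO replicates. The Slc16a3 call was lost when the 2 groups were fitted alone (adjusted p = 0.0521), and the Ankrd37 call there (0.103), without DMSO replicate 1 (0.0775) or 2 (0.0672), and without WM-1119 replicate 1 (0.0589), 2 (0.0736) or 3 (0.0724). Both calls, like that of Meaf6, were also lost without 5 libraries that held fibroblast transcripts, 1 of them WM-1119 replicate 2 of 3 days. The differences in level at 3 days did not shrink there. The WM-1119 libraries left had 2.70 and 2.73 CPM of Slc16a3, against 3.00 CPM in the one left out. For Ankrd37 the values were 1.35 and 0.735 against 1.57 CPM, and for Meaf6, which rose, 30.6 and 29.9 against 28.5 CPM.

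Over all genes, 2937 of 11997 passed the test at 3 days, 1422 higher and 1515 lower with WM-1119 (edgeR quasi-likelihood test, adjusted p below 0.05). The balance turned with upper-quartile scaling (1648 higher and 1296 lower), with no filter on low counts (1444 and 1357) and with the 2 groups fitted alone (1555 and 1496). Most changes were small: the median log2 fold change of the called genes was 0.32 in size, and 150 rose and 180 fell more than 2-fold. Calls are relative to the spread between the 3 biological replicates of each group. Directions are relative to the scaled library totals. The median log2 fold change over all genes was 0.002 at 3 days and -0.004 at 6 days, so the scaling largely sets the balance of rises and falls. A change in total messenger RNA per cell would not show.

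**Figure D1:**
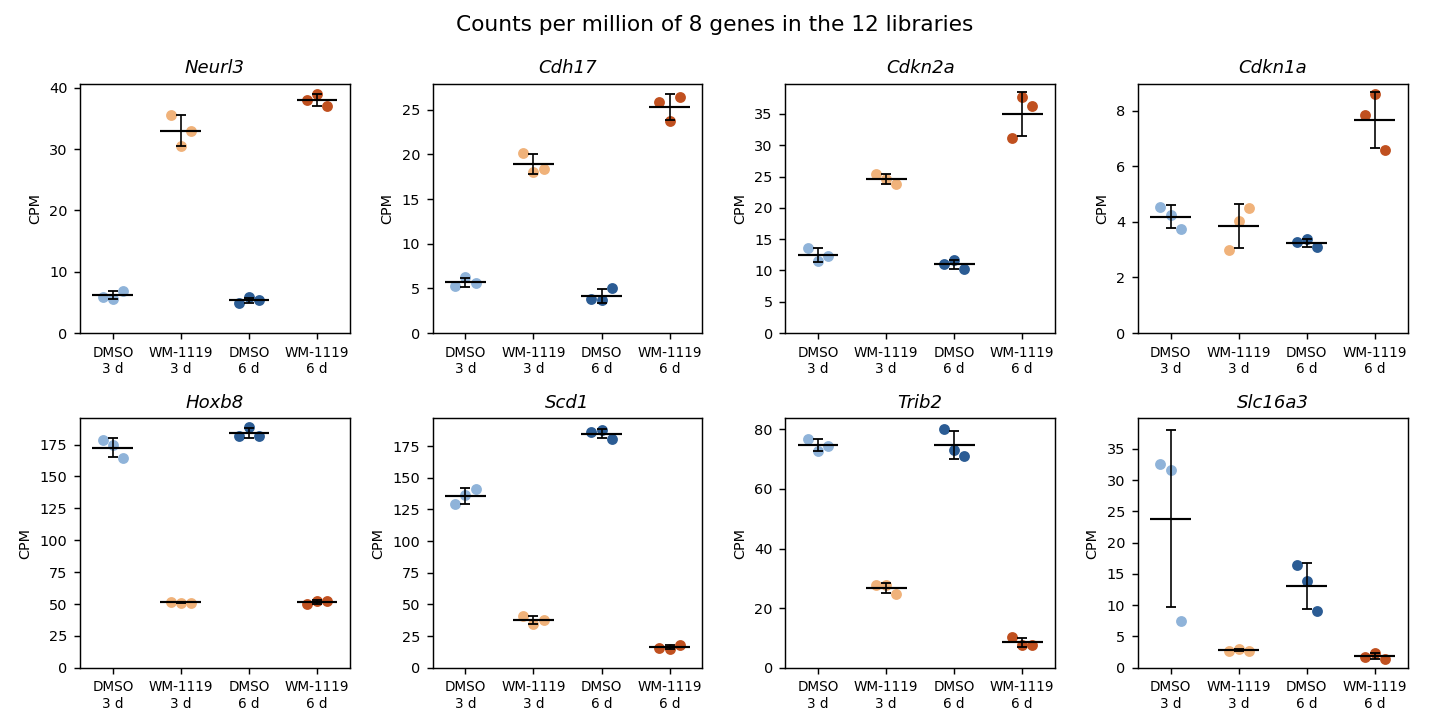
CPM of single named genes in each of the 12 libraries, with DMSO and WM-1119 at 3 and 6 days along the horizontal axis and a linear vertical axis from 0 that differs between the 8 genes. Each point is 1 library, each horizontal line is the mean of a group of 3 and the error bar is the SD; Scd1 and Trib2 lie lower at 6 than at 3 days of WM-1119, while Hoxb8 lies near 51 CPM at both.

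Genes of cholesterol and fatty acid synthesis fell together at 3 days. Of the 31 tested members 24 fell and 0 rose (adjusted over the list alone, 24 and 1), among them Cyp51 (log2 fold change -0.65) and the sterol synthesis gene Hmgcs1 (-0.58). The list was called lower than the other genes (camera adjusted p = 6.51e-16, and adjusted p = 0.144 with an estimated correlation). Glycolysis genes fell in 15 of 22 cases and rose in 2 (adjusted over the list alone, 16 and 2, adjusted p = 4.18e-07, and adjusted p = 0.281 with an estimated correlation). Pkm (-0.61), Tpi1 (-0.54) and Ldha (-0.51) fell, while the hexokinase gene Hk1 rose (0.30). The mean level of this list in DMSO replicate 3 was 0.03 on a log2 scale centred on each gene's mean over the 12 libraries, against 0.31 and 0.32 in the other DMSO replicates at 3 days. Genes of cytosolic ribosomal proteins fell in 24 of 76 cases, with 0 higher (adjusted over the list alone, 26 and 0, median -0.22; adjusted p = 2.43e-09, and adjusted p = 0.522 with an estimated correlation), Rps10 (-0.39), Rpsa (-0.34) and Rpl6 (-0.31) among them. The mean level of this list in WM-1119 replicate 3 was 0.11, against -0.07 and -0.12 in the other WM-1119 replicates and 0.15 to 0.25 with DMSO. Many ribosomal protein genes have pseudogenes, and how reads mapping to several places were handled is not given in the sources used here.

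Counts assigned to Myc fell at 3 days from 1449 ± 73.7 to 1192 ± 34.9 CPM (log2 fold change -0.28 ± 0.05; adjusted p = 0.000206). Counts per gene do not by themselves tell transcripts of the Myc transgene from those of the native gene. Of 59 tested MYC target genes 16 fell and 0 rose (adjusted over the list alone, 19 and 0), with Odc1 at -0.37 and Srm, both of polyamine synthesis, at -0.30 (adjusted p = 0.000229, and adjusted p = 0.389 with an estimated correlation). Immediate-early and dissociation stress genes fell in 8 of 20 cases and rose in 3 (adjusted over the list alone, 9 and 4), with Egr2 at -2.72, Fos at -2.52 and Ier5 at -0.78 (adjusted p = 0.0063, and adjusted p = 0.144 with an estimated correlation). Immediate-early genes respond within minutes to growth factor or antigen receptor signals, and this list also covers the stress of cell dissociation. Of 34 genes of the integrated stress response and unfolded protein response 9 fell and 2 rose (adjusted over the list alone, 11 and 2), Atf4 at -0.39 and Pdia6 at -0.32 among the lower ones and Cebpb at 0.79 among the higher ones (adjusted p = 0.012, and adjusted p = 0.281 with an estimated correlation). Markers of B cell progenitors fell in 8 of 17 cases and rose in 3 (adjusted over the list alone, 9 and 3), with Lef1 at -0.86, Bach2 at -0.73 and Sox4 at -0.46 (adjusted p = 0.0134, and adjusted p = 0.144 with an estimated correlation).

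Plasma cell genes fell in 6 of 12 cases and rose in 2 at 3 days (adjusted over the list alone, 8 and 2, adjusted p = 0.0257, and adjusted p = 0.176 with an estimated correlation). Slamf7 (-0.80) and Irf4 (-0.47) fell, and Mzb1, which encodes a chaperone of immunoglobulin assembly, rose (0.47). Genes of the G2 and M phases fell in 12 of 50 cases and rose in 2 (adjusted over the list alone, also 12 and 2), with Anln at -0.29 and Cenpa at -0.21 (adjusted p = 0.0221, and adjusted p = 0.581 with an estimated correlation). MHC class I presentation genes rose in 9 of 20 cases with 0 lower (adjusted over the list alone, 10 and 3, adjusted p = 0.0134, and adjusted p = 0.389 with an estimated correlation), Tapbp at 0.41 and H2-Q7 at 0.48, the latter in a family of near-identical paralogs. Interferon-induced genes rose in 10 of 26 cases and fell in 1 (adjusted over the list alone, 11 and 1, adjusted p = 0.012, and adjusted p = 0.144 with an estimated correlation). Ifit2 (0.88), Gbp3 (0.63) and Trim30a (0.58) rose. NF-κB target genes rose in 8 of 14 cases and fell in 1 (adjusted over the list alone, 9 and 1), with Icam1 at 0.55 and Nfkb1 at 0.25 (median 0.25, mean -0.06, called higher; adjusted p = 0.0177, and adjusted p = 0.281 with an estimated correlation). Lysosome genes rose in 13 of 39 cases and fell in 5 (adjusted over the list alone, 14 and 5, adjusted p = 0.0221, and adjusted p = 0.389 with an estimated correlation). Grn (0.65) and Psap (0.46) rose, and the protease gene Ctsl (-0.76) fell.

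In all, 13 of the 33 gene lists were called at 3 days with the preset correlation, and 0 with an estimated one. The fry test, which asks whether a list's own genes move one way without comparing them with other genes, called 16, and ended the call of the ribosomal protein list (adjusted p = 0.0764). The call of the G2 and M phase list was lost without DMSO replicate 1 at 3 days (0.0542), WM-1119 replicate 1 (0.0510) or WM-1119 replicate 3 (0.0590). Leaving out WM-1119 replicate 1 also ended the calls of the plasma cell (0.0510), NF-κB (0.0510) and lysosome (0.0783) lists. The plasma cell call was also lost without 5 libraries that held fibroblast transcripts (0.059), 1 of them WM-1119 replicate 2 of 3 days and the others of 6 days.

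The comparison at 6 days asked the same of the longer exposure. Scd1 fell 11.4-fold, from 185 ± 3.45 to 16.3 ± 1.69 CPM (SD, n = 3 each; log2 fold change -3.51 ± 0.07, SE; adjusted p = 3.29e-18). Scd2 fell 3.67-fold, from 839 ± 7.30 to 228 ± 4.17 CPM (adjusted p = 3.26e-16). Trib2, which encodes a pseudokinase that acts as an adaptor in protein degradation, fell 8.72-fold, from 74.7 ± 4.74 to 8.56 ± 1.51 CPM (adjusted p = 8.32e-16). Hoxb8 fell 3.57-fold, close to its fold at 3 days, and the histone deacetylase gene Hdac9 fell 5.68-fold. Neurl3 rose 7.17-fold, to 38.0 ± 0.935 CPM (adjusted p = 4.75e-15), and Ptgir 8.98-fold, to 13.7 ± 1.24 CPM (adjusted p = 2.24e-11).

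Ly6d rose 6.42-fold and Cdh17 6.13-fold at 6 days, and the adhesion receptor gene Adgrg1 4.45-fold. Cd86, a costimulatory ligand on B cells, rose 4.30-fold, from 2.68 ± 0.0379 to 11.6 ± 0.347 CPM. Csf2rb2, which encodes the interleukin 3 receptor beta subunit and has the close paralog Csf2rb, rose 4.18-fold, and the ERK phosphatase gene Dusp5 2.47-fold. The oxysterol-binding protein gene Osbp2 fell 7.2-fold. Igkc, the immunoglobulin kappa constant region, fell 5.18-fold, from 14.1 ± 1.08 to 2.71 ± 0.0683 CPM, and the stress-inducible gene Gadd45g fell by 2.49 on the log2 scale. Slc16a3 and Ankrd37 fell by 2.85 and 2.71 (adjusted p = 0.0204 and 0.0126). The Slc16a3 call was lost without DMSO replicate 1 at 6 days (0.0645) and without WM-1119 replicate 1 (0.0678), 2 (0.0586) or 3 (0.0686), and the Ankrd37 call without WM-1119 replicate 1 (0.0518).

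Over all genes, 3682 of 11997 passed the test at 6 days, 1881 higher and 1801 lower with WM-1119. The balance turned with no filter on low counts (1742 and 1863), with DESeq2 (1753 and 1772), without WM-1119 replicate 1 (1514 and 1565) or 2 (1493 and 1611) of 6 days. It also turned with the replicate number as a block within 6 days (2032 and 2074), a choice made after the data were seen. Their median log2 fold change was 0.34 in size, and 213 rose and 278 fell more than 2-fold. Fibroblast transcripts were present in 5 of the 12 libraries: Col1a1 reached 6.09 and 2.09 CPM in DMSO replicates 1 and 2 at 6 days, 6.80 and 12.8 CPM in WM-1119 replicates 1 and 2 at 6 days and 1.89 CPM in WM-1119 replicate 2 at 3 days, against 0.317 to 0.977 CPM in the others. With those 5 libraries left out, a choice made after the values were seen, the comparison at 6 days rested on 1 library against 1 and called 1436 genes. The calls at 6 days of Slc16a3, Ankrd37, Brpf3, Cdc6, Cdkn1b, Srm, Cd74 and Rpl6 were lost there (adjusted p from 0.0508 to 0.611). Their log2 fold changes there were -2.65, -1.75, 0.31, -0.22, -0.15, -0.28, 0.63 and -0.22, against -2.85, -2.71, 0.23, -0.27, -0.46, -0.30, 0.71 and -0.35 with all libraries.

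**Figure D2:**
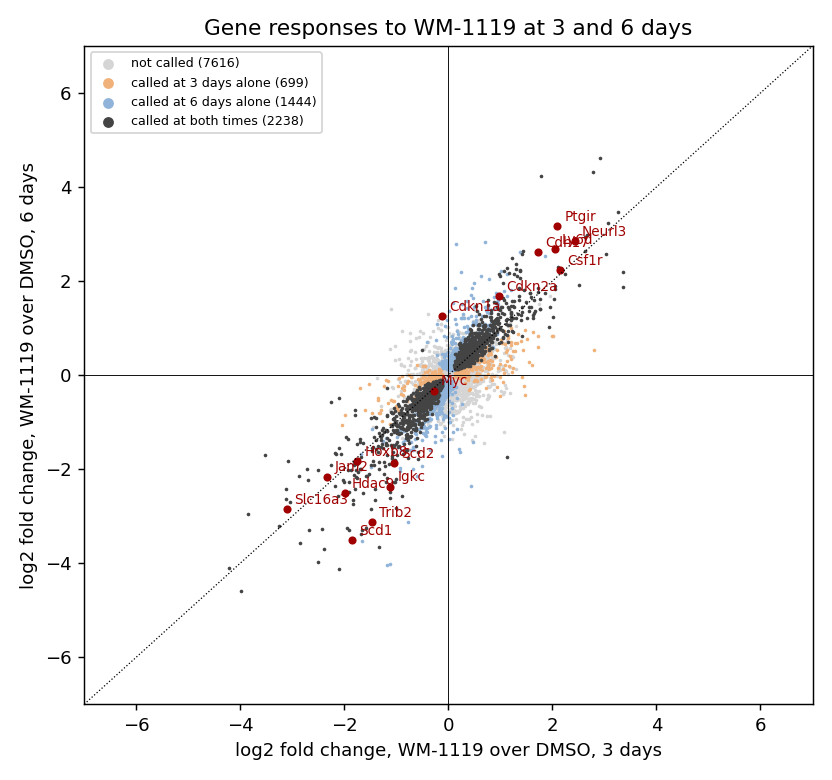
Log2 fold change of WM-1119 over DMSO at 3 days (horizontal axis) against 6 days (vertical axis), each point 1 of the 11997 tested genes, coloured by the times at which it passed the test, with the line of equal change dotted. Most of the genes called at both times lie in the quadrants of like direction, and Hoxc4, with 0 counts in all DMSO libraries, lies outside the axes.

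Cholesterol and lipid synthesis genes fell in 26 of 31 cases at 6 days, with 0 higher (adjusted over the list alone, also 26 and 0, median -0.72; adjusted p = 2.38e-23, and adjusted p = 0.0421 with an estimated correlation). Cyp51 (-1.03) and Hmgcs1 (-0.96, from 178 to 91.5 CPM) fell. Interferon-induced genes rose in 16 of 26 cases and fell in 1 (adjusted over the list alone, also 16 and 1, median 0.25; adjusted p = 3.23e-06, and adjusted p = 0.0155 with an estimated correlation). Among them were genes of guanylate-binding proteins, GTPases of cell-autonomous defence with close paralogs, with Gbp7 at 1.48, Gbp2 at 1.36 and Gbp3 at 1.18, as well as Ifit2 at 1.09 and Trim30a at 0.78. These were the 2 list calls at 6 days that held with an estimated correlation.

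Genes of cytosolic ribosomal proteins fell in 44 of 76 cases at 6 days, with 0 higher (adjusted over the list alone, 62 and 0, median -0.41; adjusted p = 2.47e-15, and adjusted p = 0.34 with an estimated correlation), Rps10 at -0.43 and Rpl6 at -0.35 among them. The mean level of this list in DMSO replicate 3 at 6 days was -0.16 on the centred log2 scale, against 0.24 and 0.34 in the other DMSO replicates. With WM-1119 it was -0.31, -0.18 and -0.39, so DMSO replicate 3 lay close to WM-1119 replicate 2. Glycolysis genes fell in 15 of 22 cases and rose in 2 (adjusted over the list alone, 18 and 2, adjusted p = 3.23e-06, and adjusted p = 0.273 with an estimated correlation). Pkm (-0.69), Tpi1 (-0.54) and Ldha (-0.53) fell, and Hk1 (0.44) rose. Here too DMSO replicate 3 had the lowest mean level of the DMSO group, 0.10 against 0.25 and 0.29. MYC target genes fell in 24 of 59 cases with 0 higher (adjusted over the list alone, also 24 and 0, adjusted p = 1.44e-05, and adjusted p = 0.3 with an estimated correlation), Odc1 at -0.33, Srm at -0.30 and the nucleophosmin gene Npm1 at -0.29. Stress response genes fell in 18 of 34 cases and rose in 5 (adjusted over the list alone, also 18 and 5, adjusted p = 0.00139, and adjusted p = 0.242 with an estimated correlation). Atf3 (-2.66) and Pdia6 (-0.33) fell, and Cebpb (0.79) rose. Immediate-early and dissociation stress genes fell in 9 of 20 cases and rose in 2 (adjusted over the list alone, 10 and 2, adjusted p = 0.0115, and adjusted p = 0.223 with an estimated correlation). Fos (-2.03) and Egr1 (-1.64) fell. Plasma cell genes fell in 7 of 12 cases and rose in 2 (adjusted over the list alone, 7 and 3, adjusted p = 0.0449, and adjusted p = 0.261 with an estimated correlation). Slamf7 (-1.26) and Irf4 (-0.71) fell, and Mzb1 (0.65) rose.

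MHC class I genes rose in 13 of 20 cases at 6 days with 0 lower (adjusted over the list alone, also 13 and 0, median 0.21; adjusted p = 4.52e-05, and adjusted p = 0.242 with an estimated correlation). Tapbp (0.49) and H2-Q7 (0.44) rose. MHC class II genes rose in 3 of 9 cases with 0 lower (adjusted over the list alone, also 3 and 0, adjusted p = 0.0402, and adjusted p = 0.261 with an estimated correlation), H2-Eb2 at 1.08 and the invariant chain gene Cd74 at 0.71 among them. Their levels at 6 days were low. H2-Eb2 had 5.00 to 5.94 CPM with DMSO and 10.8 to 12.7 CPM with WM-1119, and Cd74 had 2.37 to 3.10 and 3.89 to 4.92 CPM. At 3 days 1 of the 9 MHC class II genes had risen, H2-Eb2 at 0.58, and the list was not called (adjusted p = 0.615). NF-κB target genes rose in 7 of 14 cases and fell in 1 (adjusted over the list alone, also 7 and 1, adjusted p = 0.0182, and adjusted p = 0.273 with an estimated correlation). Icam1 (0.53) and Tnip1 (0.51) rose. Lysosome genes rose in 14 of 39 cases and fell in 4 (adjusted over the list alone, 15 and 6, adjusted p = 0.039, and adjusted p = 0.373 with an estimated correlation). Grn (0.61) and Psap (0.58) rose, and Ctsl (-0.95) fell.

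In all, 12 lists were called at 6 days with the preset correlation and 23 by fry. The MHC class II call was lost without DMSO replicate 1 (0.0680), DMSO replicate 3 (0.0614) or WM-1119 replicate 2 (0.0781) of 6 days, with all libraries thinned to the same depth (0.171), with no filter on low counts (0.0563) and without the 5 libraries with fibroblast transcripts (0.0979). The lysosome call was lost without the same 3 libraries (0.0643, 0.0614 and 0.0696) and with no filter (0.0614), and the plasma cell call without WM-1119 replicate 1 (0.0518) or 3 (0.0517) of 3 days, DMSO replicate 3 of 6 days (0.0666) or WM-1119 replicate 1 (0.131) or 2 (0.0696) of 6 days, and with the replicate number as a block within 6 days (0.0563).

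**Figure D3:**
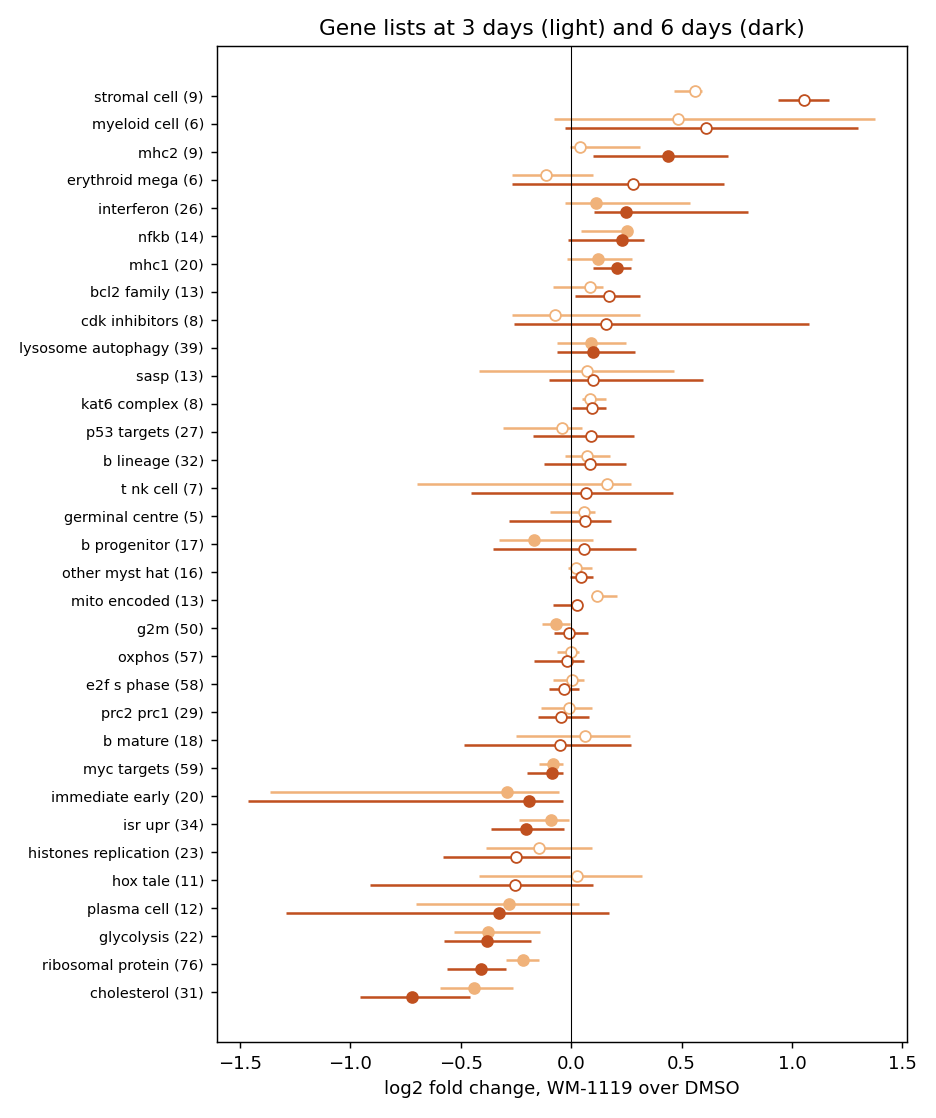
Median log2 fold change of WM-1119 over DMSO over the tested members of each gene list, at 3 and 6 days. Lines span the lower to the upper quartile of the members, numbers in parentheses are the members tested, and filled points mark lists called against the other genes by camera with a preset correlation; the sterol list (cholesterol) has the lowest median at both times.

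Genes of cell cycle arrest went in both directions. Cdkn2a, which encodes p16INK4a and p19ARF, rose 1.97-fold at 3 days, from 12.5 ± 1.1 to 24.7 ± 0.821 CPM (log2 fold change 0.98 ± 0.09; adjusted p = 7.97e-08), and 3.19-fold at 6 days, from 11 ± 0.753 to 35.0 ± 3.45 CPM (adjusted p = 1.19e-11). Cdkn1a, which encodes p21, had a log2 fold change of -0.12 ± 0.16 at 3 days (adjusted p = 0.647) and rose 2.38-fold at 6 days, from 3.24 ± 0.143 to 7.68 ± 1.01 CPM (adjusted p = 1.17e-06). Cdkn2c fell at 3 days (-0.39) and Cdkn1b at 6 days (-0.46). Of 8 cyclin-dependent kinase inhibitor genes 2 were higher and 1 lower at 3 days, and 4 and 2 at 6 days, and the list was not called by camera (adjusted p = 0.877 and 0.386), while fry called it at 6 days (adjusted p = 0.276 and 0.00172). At 3 days its median was -0.07, its mean 0.23 and the direction of camera up. Trp53 did not pass the test (0.13 and 0.08; adjusted p = 0.0545 and 0.216). At 3 days it did pass without DMSO replicate 3 of 3 days (0.0325) or of 6 days (0.0464), and also with 6 of the other alternatives, with the lowest adjusted p from upper-quartile scaling (0.0191). Of 27 p53 target genes 2 were higher and 7 lower at 3 days, and 7 and 7 at 6 days (list adjusted p = 0.0733 and 0.842 by camera). Of 13 genes of the senescence-associated secretory phenotype 1 was higher and 3 lower at 3 days, and 3 and 3 at 6 days (0.869 and 0.421).

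Among proliferation genes Mki67 had log2 fold changes of 0.05 and 0.17 and Melk of -0.02 and 0.12, and neither passed the test, except that Mki67 did at 6 days when the 2 groups were fitted alone (adjusted p = 0.0493) or without WM-1119 replicate 1 of 3 days (0.0250). E2F targets and S phase genes were higher in 6 and lower in 8 of 58 cases at 3 days, and in 4 and 12 at 6 days (list adjusted p = 0.877 and 0.319), with Cdc6, a licensing factor of replication origins, at -0.27 at 6 days (adjusted p = 0.00023). Genes of the G2 and M phases, lower as a list at 3 days (adjusted p = 0.0221, and adjusted p = 0.581 with an estimated correlation), were higher in 4 and lower in 3 of 50 cases at 6 days (adjusted p = 0.927). Ezh2, the methyltransferase of the polycomb repressive complex PRC2, fell at both times (-0.36 ± 0.05 and -0.35 ± 0.05; adjusted p = 7.19e-06 and 8.82e-06), while of 29 polycomb genes 4 were higher and 5 lower at 3 days and 4 and 7 at 6 days (0.867 and 0.571). Genes of the other MYST acetyltransferases and their partners were higher in 2 of 16 cases at 3 days and in 1 at 6 days, with 0 lower (0.379 and 0.252). Nuclear genes of oxidative phosphorylation were higher in 0 and lower in 3 of 57 cases at 3 days, and in 2 and 3 at 6 days (0.877 and 0.758). Of 23 genes of replication-dependent histones, whose transcripts mostly lack the poly(A) tail that the libraries select, 2 fell at 3 days and 3 at 6 days (0.507 and 0.188). Of the 13 genes of the mitochondrial genome 0 were called at either time (0.253 and 0.892).

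B cell identity genes moved in both directions. Of 32 B lineage genes 10 were higher and 6 lower at 3 days, and 15 and 9 at 6 days (list adjusted p = 0.227 and 0.251), with the antigen receptor subunit gene Cd79b higher (0.51 and 0.48) and the lineage regulator gene Pax5 (-0.47 and -0.58) and Fcrla (-0.66 and -0.71) lower. Progenitor markers at 6 days were higher in 7 and lower in 7 of 17 cases (adjusted p = 0.648; median 0.06, test direction down), with Bach2 at -1.07 and Lef1 at -0.88. Mature B cell genes were higher in 4 and lower in 4 of 18 cases at 3 days, and in 7 and 5 at 6 days (0.867 and 0.84), and germinal centre genes higher in 1 and lower in 1 of 5 at 3 days and in 1 and 2 at 6 days (0.879 and 0.954). Of 7 T and NK cell genes 1 was higher and 2 lower at both times (0.879 and 0.842), with Cd2 at 0.55 and 0.57 and Klrb1c at -1.80 and -0.84. Of 9 stromal cell genes 0 were higher and 1 lower at 3 days, and 0 and 2 at 6 days (0.879 and 0.827; medians 0.56 and 1.06, test direction down). The chemokine gene Cxcl12 fell at both times (-2.85 and -3.56). Median, mean and test also differed in sign for the uncalled E2F, secretory phenotype, mature B cell, germinal centre, polycomb and T and NK cell lists at 3 days, and for the uncalled p53 target, mature B cell, germinal centre, mitochondrial and T and NK cell lists at 6 days.

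The folds at 3 and 6 days were then set against each other. Neurl3, Ptgir, Ly6d, Cdh17, Tal1 and Dusp5 rose and Scd1, Scd2, Hoxb8 and Hdac9 fell at both times. In all, 2236 genes were called in the same direction at both times, 1114 higher and 1122 lower, where independent calls would give 450.4. This was 76.1% of the calls at 3 days. The Pearson correlation of the log2 fold changes across the 11997 genes was 0.787 and Spearman's rho 0.712, where genes are not independent replicates. Among the shared genes 1471, or 65.8%, had the larger fold at 6 days, with a median ratio of 1.12. A further 699 genes were called at 3 days alone and 1444 at 6 days alone, which is not by itself a test of a difference. In opposite directions 2 genes were called, named here after their values were seen: Cd300ld fell at 3 days (-0.50; adjusted p = 0.000412) and rose at 6 days (0.54; adjusted p = 2.45e-05), and the small nucleolar RNA gene Snora61 rose at 3 days (1.12; adjusted p = 0.0327) and fell at 6 days (-1.74; adjusted p = 0.00738). With both times averaged, 5027 genes passed the test, 2467 higher and 2560 lower, with a median log2 fold change of 0.26 in size. With upper-quartile scaling 2794 were higher and 2218 lower, and without the 5 libraries with fibroblast transcripts 1641 and 1603. The balance turned in both. Without the 5 libraries with fibroblast transcripts these counts were 1087 shared genes and 3244 genes over both times.

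Whether the response differed between the times was tested as the difference of the log2 fold changes, 6 days minus 3 days. The fall of Scd1 was larger at 6 days by -1.66 ± 0.09 on the log2 scale (SE; adjusted p = 1.81e-09), that of Trib2 by -1.65 ± 0.12 (adjusted p = 7.47e-08) and that of Scd2 by -0.83 ± 0.07 (adjusted p = 6.18e-07). Cmah, which encodes the hydroxylase that makes N-glycolylneuraminic acid, went from 77.9 to 45.4 CPM at 3 days and from 92.8 to 35.8 CPM at 6 days (-0.60 ± 0.08; adjusted p = 0.000658). The myeloid receptor gene Cd300ld (1.04 ± 0.12), the actinin gene Actn1 (0.49 ± 0.06), the phospholipase gene Plce1 (1.00 ± 0.14) and the imprinted noncoding RNA gene H19 (0.92 ± 0.13) had the smallest p-values among the positive differences. Without the 5 libraries with fibroblast transcripts the calls of Cd300ld, Actn1, H19 (adjusted p = 0.167 each), Plce1 (0.0656) and Cmah (0.436) were lost, with differences of 0.95, 0.47, 0.88, 1.18 and -0.47 and 1 library per treatment left at 6 days.

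In all, 83 of 11997 genes differed between the times, 47 with a higher and 36 with a lower log2 fold change at 6 days, and 986 did at an unadjusted p below 0.05. The balance turned with no filter on low counts (39 and 44), without DMSO replicate 3 of 6 days (92 and 123) and without the libraries with fibroblast transcripts (0 and 4). It was even without WM-1119 replicate 1 of 6 days (22 and 22). Of 31 cholesterol and lipid synthesis genes 13 had a lower log2 fold change at 6 days and 0 a higher one (adjusted over the list alone, 22 and 0, median -0.32; adjusted p = 7.08e-30, and adjusted p = 0.0208 with an estimated correlation). Interferon-induced genes had a median difference of 0.19, with 1 of 26 higher and 0 lower (adjusted over the list alone, 4 and 0; adjusted p = 5.74e-06, and adjusted p = 0.0150 with an estimated correlation). The mean level of this list with DMSO was -0.09 to -0.04 on the centred log2 scale at 3 days and -0.28 to -0.22 at 6 days. With WM-1119 it was 0.11 to 0.13 and 0.11 to 0.23, so the difference includes a fall in the DMSO libraries. The sterol and interferon calls were the 2 of 7 list calls that held with an estimated correlation. The other 5 were those of MHC class II (0.24; adjusted p = 0.0162, and adjusted p = 0.227 with an estimated correlation), MHC class I (0.08; 0.0162, and adjusted p = 0.501 with an estimated correlation), p53 target (0.08; 0.00042, and adjusted p = 0.143 with an estimated correlation), G2 and M phase (0.06; 0.00145, and adjusted p = 0.536 with an estimated correlation) and ribosomal protein genes (-0.16; 3.22e-05, and adjusted p = 0.72 with an estimated correlation). Of the p53 targets 3 of 27 were called higher and 0 lower (adjusted over the list alone, 5 and 0), and in the other 4 lists 0 members were called either way. The MHC class II call was lost without DMSO replicate 2 (0.0501) or WM-1119 replicate 2 (0.0870) of 3 days or DMSO replicate 3 of 6 days (0.0789), the MHC class I call without DMSO replicate 2 of 3 days (0.0847), DMSO replicate 3 (0.206) or WM-1119 replicate 2 (0.110) of 6 days, and the ribosomal protein call without DMSO replicate 2 of 6 days (0.0785). Without the libraries with fibroblast transcripts all 5 except the MHC class I call were lost (adjusted p from 0.0892 to 0.225). The number of genes was 4 without the libraries with fibroblast transcripts, 215 without DMSO replicate 3 of 6 days, and 39 to 55 without any one of the others except DMSO replicate 3 of 3 days (61) and WM-1119 replicate 1 of 3 days (72).

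The DMSO groups were compared with each other to see what differed between 3 and 6 days without the inhibitor. Col1a1 had 6.09 and 2.09 CPM in DMSO replicates 1 and 2 of 6 days, against at most 0.977 CPM with DMSO at 3 days. Library totals were 22831687 to 41749357 counts at 6 days and 17928095 to 21712496 at 3 days. The comparison is therefore not one of time in culture alone. Scd2 rose from 609 ± 44.5 to 839 ± 7.30 CPM between 3 and 6 days of DMSO (log2 fold change 0.46 ± 0.05, SE; n = 3 each; adjusted p = 8.11e-05) and Scd1 from 136 ± 6.15 to 185 ± 3.45 CPM (0.45 ± 0.06; adjusted p = 0.000821). Of 31 cholesterol and lipid synthesis genes 15 rose and 0 fell (adjusted over the list alone, 23 and 1, median 0.29; adjusted p = 4.11e-26, and adjusted p = 0.0444 with an estimated correlation). The DNA sensor gene Aim2 (0.64) and Ly86 (0.79), whose product partners a toll-like receptor homologue on B cells, rose. Nlgn2 (-0.65), Carmil2 (-0.53), Camk2b (-0.51) and Micall2 (-0.48) fell.

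Between the DMSO groups 101 genes passed the test, 46 higher and 55 lower at 6 days, and 1560 did at an unadjusted p below 0.05. Interferon-induced genes were called lower as a list (median -0.11; adjusted p = 0.00107, and adjusted p = 0.0444 with an estimated correlation), with 0 members called over all genes and 5 lower adjusted over the list alone. The interferon call was lost without the libraries with fibroblast transcripts, where 1 DMSO library was left at 6 days. The mean level of the list in that library was -0.28 on the centred log2 scale, against -0.22 and -0.24 in the DMSO libraries left out. Stromal cell genes were called higher (median 2.16; adjusted p = 0.0419, and adjusted p = 0.775 with an estimated correlation), with mean levels of 1.69 and 0.96 on the centred log2 scale in DMSO replicates 1 and 2 of 6 days and of -1.27 in replicate 3. This call was lost without DMSO replicate 3 of 3 days (0.0937), DMSO replicate 1 (0.448) or 2 (0.120) of 6 days, WM-1119 replicate 1 (0.142) or 3 (0.110) of 3 days, or WM-1119 replicate 1 (0.141) or 2 (0.0722) of 6 days. In all 9 lists were called, among them E2F target and S phase genes higher (adjusted p = 0.00187, and adjusted p = 0.425 with an estimated correlation) and G2 and M phase genes lower (adjusted p = 1.39e-06, and adjusted p = 0.388 with an estimated correlation). The first was lost without DMSO replicate 2 of 6 days (0.0543), the second without the libraries with fibroblast transcripts (0.61), and both with fry (0.0967). With upper-quartile scaling, 44 genes were higher and 90 lower, so that 32.8% of the calls were rises against 45.5% with the main scaling. The balance turned with limma voom (46 and 43), with the 2 groups fitted alone (26 and 21) and without any one of 9 of the 12 libraries, most of all DMSO replicate 2 of 3 days (26 and 14) and DMSO replicate 3 of 6 days (38 and 26). It is not settled here. Without DMSO replicate 1 of 6 days it was 43 and 107. The number of calls was 35 without DMSO replicate 1 of 3 days, 40 without replicate 2 of 3 days and 64 without replicate 3 of 6 days, 171 with DESeq2, 47 with the 2 groups fitted alone, 222 with the replicate number as a block within 6 days and 498 without the libraries with fibroblast transcripts.

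**Figure D4:**
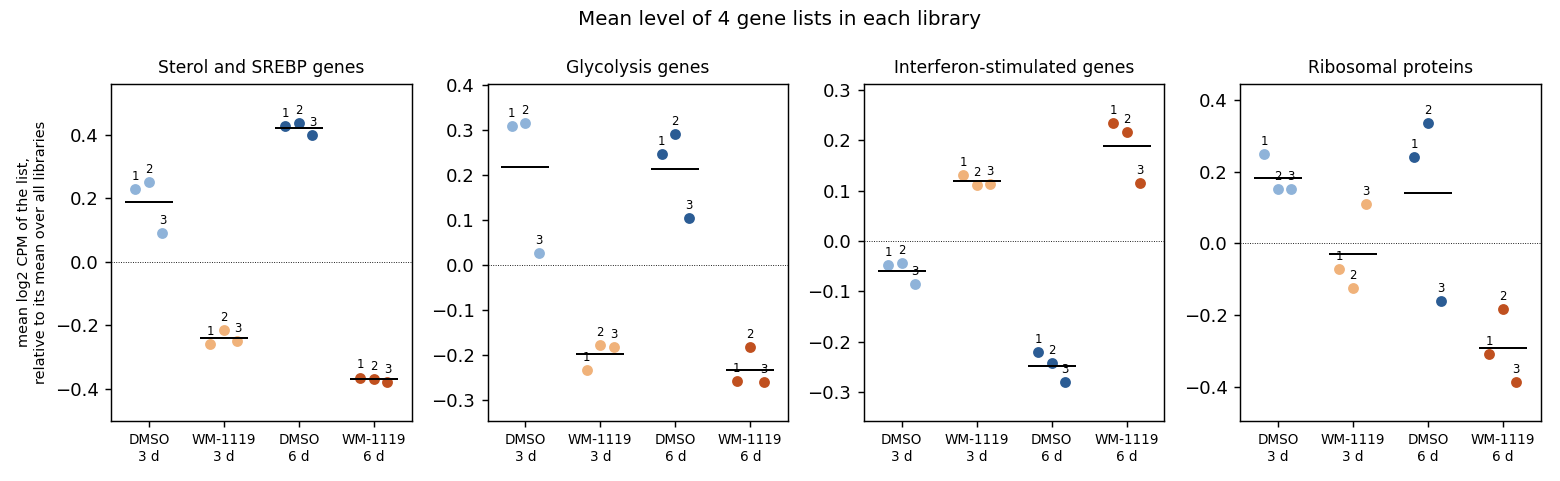
Mean level of gene lists in each of the 12 libraries, as log2 CPM centred on each gene's mean over all libraries, with the groups along the horizontal axis. Each point is 1 library, and DMSO replicate 3 lies below the other DMSO replicates of its time for the glycolysis list.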

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

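Apart from the counts of sample splits, which were planned before the data were examined, the tests of explanations below were chosen after the results were seen. Of 203 genes named for an effect of WM-1119 or for its difference between the times, 25 had an effect of WM-1119 that differed between 3 and 6 days by the test of the difference itself (n = 3 libraries per group), 5 of them named by that test alone, and 7 gene lists did so by camera, 2 of them (sterol synthesis and interferon-induced genes) also with an estimated correlation. All values are differences of log2 fold changes, 6 days minus 3 days.

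Genes with a larger fall at 6 days were Scd1 (-1.66), Trib2 (-1.65), Osbp2 (-1.36), Igkc (-1.25), Scd2 (-0.83), Slamf7 (-0.46), Cyp51 (-0.38), Hmgcs1 (-0.38) and Bach2 (-0.34). Genes with a larger rise at 6 days were Cdkn2a (0.69), Cd86 (0.78), Gbp2 (0.81), Cdh17 (0.89), Apbb1 (1.11), Adgrg1 (1.17) and the germinal centre gene Gcsam (0.45). Cdkn1a was called at 6 days and not at 3 days (1.37). The falls of Nr4a3 (1.61) and Ephx1 (1.06) were smaller at 6 days, and Enpep (0.32) had log2 fold changes of -0.33 at 3 days and near 0 at 6 days. The genes named by the test alone were Cmah (-0.60), Actn1 (0.49), H19 (0.92), Plce1 (1.00) and Cd300ld (1.04). Without the 5 libraries with fibroblast transcripts, which leaves 1 library per treatment at 6 days, 0 positive and 4 negative differences were called over all genes. All the positive differences given here and most of the negative ones lost their call there, while those of Scd1, Trib2 and Scd2 kept it. Among the lists the median difference was -0.32 for sterol synthesis and SREBP targets, -0.16 for ribosomal proteins, 0.24 for MHC class II, 0.19 for interferon-induced genes, 0.082 for MHC class I, 0.076 for p53 targets and 0.055 for the G2 and M phases.

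Splits of the samples other than the real one bear on the number of such genes. With the time labels redrawn within each treatment, 5 of 100 splits, the real one included, called at least the 83 genes of the real split. The others gave 1030, 684, 270 and 262. The split with 1030 exchanged the times in the WM-1119 cultures only, which turns the difference into the change with time shared by both treatments. It so points to a structure of the samples by time. Those with 684 and 262 also exchanged 1 DMSO library of each time. The split with 270 exchanged most of the times in the DMSO cultures only. Such splits carry the shared change with time, so the share of 5 in 100 does not decide on chance. Chance is not excluded for this count. For the average over both times, 1 of 100 splits, the real one, reached 5027 genes and the highest other gave 1584. This argues against chance at a share of 1 in 100 drawn splits. Splits that mix the treatments hold the treatment effect within their groups, which can lower their counts. A difference shared by all libraries of a treatment stays open. The comparisons at 3 days, at 6 days and of DMSO over time allow 10 splits each, too few for a share under 0.05. The real split was the 1 with the most calls in each, with 2937, 3682 and 101 genes against at most 0, 0 and 2 in the others.

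The larger fall of the sterol genes at 6 days was weighed against a change of the DMSO cultures and against depth. From 3 to 6 days the median log2 change of the 31 genes was 0.29 in DMSO and -0.070 in WM-1119, so most of the difference is consistent with a rise in the DMSO cultures that the WM-1119 cultures lacked. The list was not flat in WM-1119, where camera called it lower (adjusted p = 0.00443, and adjusted p = 0.625 with an estimated correlation), with 3 genes lower and 0 higher. Scd1 fell by 1.21 ± 0.08 (SE; -1.21 on the log2 scale; adjusted p = 5.10e-09) within the WM-1119 cultures. Scd2 (-0.37, adjusted p = 0.000232) and Tm7sf2 (-0.82, adjusted p = 0.00869), the latter named after its values were seen, also fell there. With all libraries thinned to 14691369 counts the median difference was -0.31, and 9 of the genes were called lower, against 13 with all counts. Thinning keeps each gene's expected share of a library. The size of the difference could therefore hardly move, and it does not decide on depth as a cause. Medium use, cell density and feeding differ with time in ways the labels do not give and stay open, as does a slower effect of the inhibitor.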

How the results depend on the processing

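The alternatives that thin the libraries, leave out those with fibroblast transcripts or block by number within 6 days were chosen after the data were seen. Leaving out each library in turn gave 2132 to 3259 genes at 3 days, 2918 to 3798 at 6 days, 4469 to 5137 over both times, 39 to 215 for the difference between times, 35 to 150 for DMSO over time, 1759 to 2190 shared genes, and 9 to 14 and 9 to 12 lists at 3 and 6 days. The count for the difference was highest without DMSO replicate 3 of 6 days and lowest without WM-1119 replicate 3 of 6 days, and that for DMSO was lowest without DMSO replicate 1 of 3 days. With the 5 libraries with fibroblast transcripts left out, there were 1436 genes at 6 days, 3244 over both times, 4 for the difference, 498 for DMSO over time and 1087 shared. At 6 days 1 library per treatment is then left and is assumed to vary like the other groups. DMSO over time gave 171 genes with DESeq2 and 47 with its 2 groups fitted alone, for which the cause was not tested. With an estimated correlation 0 lists were called at 3 days and 2 at 6 days, and fry, which does not compare with other genes, called 23 at 6 days. With the replicate number as a block the counts were 3150, 3881, 5202, 95 and 141 genes, 2383 shared and 13 and 12 lists. As a block within 6 days, where same-numbered libraries deviate together, it gave 3273, 4106, 5400, 107 and 222 genes, 2469 shared and 13 and 11 lists. It ended the call of the plasma cell list at 6 days (adjusted p = 0.0563), made a call of the difference between times for the mitochondrially encoded genes (0.0112) and of Col5a1 and Postn at 6 days, and changed the call of no other named gene or list at 6 days or for the difference. Libraries thinned to 14691369 counts gave 2625, 3398, 4742, 62 and 75 genes, so the counts fell by less than 1.5 times at that depth. Thinning only removes reads and cannot tell how many genes deeper libraries would call.

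Of 321 results for named genes 69 changed their side of the threshold in at least 1 alternative and 0 changed direction. Of 132 results for lists 69 changed side, 35 of them with an estimated correlation, and 5 reversed in direction. Without the fibroblast-transcript libraries these were the test's direction for the mitochondrially encoded genes at 6 days (adjusted p = 0.0106), whose median stayed above 0 (0.22), and the direction for the stromal genes of DMSO over time (median -0.55). The others came from leaving out 1 library. The stromal median for the difference between times ran from -0.38 (without WM-1119 replicate 2 of 6 days) to 1.17 (without DMSO replicate 1 of 6 days), and the test's direction turned without WM-1119 replicate 3 of 6 days (median 1.00, adjusted p = 0.0474). For DMSO over time the glycolysis median ran from -0.053 (without DMSO replicate 3 of 3 days) to 0.050 (without DMSO replicate 1 of 3 days). The ribosomal protein median there ran from -0.092 (without DMSO replicate 2 of 6 days) to 0.074 (without DMSO replicate 3 of 6 days). Fewer samples entered each of these, and the cause was not tested further. With RLE and upper-quartile scaling the median log2 fold change of all genes moved by at most 0.02.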

Other observations

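The tests of explanations in this part and the list of hypoxia-induced genes were chosen after the results were seen. Several genes of other blood lineages changed in these B cells. The macrophage growth factor receptor gene Csf1r rose by 2.14 ± 0.20 on the log2 scale at 3 days (SE, n = 3 libraries per group; from 1.04 to 4.66 CPM) and by 2.23 ± 0.20 at 6 days, and the Fc receptor gene Fcgr3 rose by 0.86 and 1.13, while the macrophage mannose receptor gene Mrc1 fell (-1.02 and -0.88). Tyrobp, an adaptor of myeloid and NK receptors, rose by 1.55 and 1.35, at 6 days with an adjusted p of 0.0125 that became 0.0676 without DMSO replicate 1 and 0.0687 without WM-1119 replicate 3 of 6 days, and 0.0516 without the libraries with fibroblast transcripts. Of 6 tested myeloid markers 3 were higher and 2 lower at 3 days, and 3 and 1 at 6 days, and the list was not called by camera (adjusted p = 0.466 and 0.181). Tal1, a transcription factor gene of early blood, erythroid and megakaryocytic cells, rose 2.74-fold at 3 days, from 5.80 to 16 CPM, and 3.53-fold at 6 days, from 7.04 to 24.4 CPM. Of the 6 erythroid and megakaryocytic markers 1 was higher and 0 lower at 3 days, and 2 and 1 at 6 days (0.869 and 0.252; at 3 days the median was -0.12, the mean 0.074 and the test's direction up).

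Homeobox genes changed in both directions. Of 11 tested HOX and TALE genes 3 were higher and 4 lower at 3 days, and 3 and 5 at 6 days (list adjusted p = 0.615 and 0.17 by camera, and 0.000398 and 0.000147 by fry; at 3 days the median was 0.03, the mean 0.46 and the test's direction down, and at 6 days -0.25, 0.47 and down, with both means above 0 through Hoxc4 alone). Within the Hoxb cluster Hoxb8 (-1.75 and -1.83), Hoxb7 (-1.19 and -1.16) and Hoxb3 (-0.32 and -0.83) fell at both times, while Hoxb4, Hoxb5 and Hoxb6 did not pass the test. Of these Hoxb3, Hoxb4, Hoxb5 and Hoxb6 were named after their values were seen. Hoxc4 had 0 counts in all 6 DMSO libraries and 36 and 94 counts in the WM-1119 libraries of 3 and 6 days, at least 11.1-fold and 57.4-fold higher against a floor of 3 counts over the group (adjusted p = 0.000395 and 1.3e-07). The HOX partner gene Pbx3, named after its values were seen, rose by 1.38 and 2.24. Of 13 BCL-2 family genes 3 were higher and 1 lower at 3 days, and 6 and 2 at 6 days (0.639 and 0.244; at both times the median was above 0, the mean below 0 and the test's direction up). Pmaip1, which encodes the BH3-only protein NOXA, fell by 1.39 ± 0.11 and 1.58 ± 0.11 (from 22.2 to 8.43 CPM and from 24.5 to 8.17 CPM), Bcl2l11, which encodes BIM, rose by 0.20 and 0.35, and Bcl2 fell at 6 days (-0.62, a call lost without the libraries with fibroblast transcripts, adjusted p = 0.415).

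Fibroblast transcripts stood out in 5 libraries from both treatments, with Col1a1 at 12.8 CPM in WM-1119 replicate 2 and 6.09 CPM in DMSO replicate 1 of 6 days. An effect of WM-1119 as the whole cause is argued against, as libraries of both treatments held them. At 3 and 6 days 0 of the 7 fibroblast matrix genes were called, which decides little given the spread within groups. At 6 days Col1a1 ranged from 0.405 to 12.8 CPM with WM-1119 and from 0.488 to 6.09 CPM with DMSO. With the replicate number as a block within 6 days Col5a1 (1.55, adjusted p = 0.000131) and Postn (1.38, adjusted p = 0.00944) were called higher at 6 days. A part played by WM-1119 therefore stays open. The 7 genes rose and fell together: the lowest of 6 Pearson correlations with Col1a1 over the 12 libraries was 0.866 (Postn; Spearman's rho 0.881; permutation p = 8e-05 and 0.00039; adjusted p = 0.00012), and 0.733 without the 2 libraries farthest from the median of Col1a1. RNA or reads of 1 other source, such as fibroblasts, may therefore have entered these libraries, which is a hypothesis from the same data. Whether it entered in the culture or in the preparation stays open.

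The fall of the glycolysis genes may reflect a weaker hypoxia response of the WM-1119 cultures. Of 19 textbook targets of hypoxia-inducible factors outside the glycolysis list, 13 fell and 0 rose at 3 days and 14 fell and 1 rose (Car9) at 6 days, and the median nearer to 0 was -0.53 at 3 days, against -0.59 at 6 days. Ankrd37 and Ndrg1, of this list, were already known to have fallen. The mean level of the 19 targets in DMSO replicate 3 lay apart from replicates 1 and 2 on the centred log2 scale, at -0.10 against 0.65 and 0.61 at 3 days and at 0.26 against 0.61 and 0.58 at 6 days, and above the highest WM-1119 library (-0.39). Differences between single samples unrelated to the inhibitor were examined as the whole cause of the fall of the glycolysis genes. With the treatment labels redrawn within each time, 2 of 400 splits, the real one and its mirror image, gave a difference in the list's mean level as large as the real one (permutation p = 0.005). Every DMSO library lay above every WM-1119 library at both times, which fixed this share at its lowest possible value. As the list was followed up because it fell, the share restates that separation and is no independent support. The size of the fall at 3 days is less certain, as the gap between the lowest DMSO and the highest WM-1119 library was 0.204 there, within the range of 0.290 over the DMSO libraries, while at 6 days the gap was 0.286 and the range 0.187. A difference shared by all samples of a treatment stays open. Fewer cells per culture with WM-1119 would leave more oxygen and was not measured in these data.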
